A study of Arabidopsis thaliana with 4 samples.

How the data were processed

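Whole seedlings of Col-0 and of an *ECT2* T-DNA insertion line were harvested at 14 days, with 2 libraries per genotype. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was isolated on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned with TopHat to TAIR10, without versions. The quantifier, the annotation release and any scaling between libraries are not given in the sources used here. The authors deposited 1 table per library, whose values are taken here to be FPKM. That unit is inferred: the header has an identifier column named as in Cufflinks tables, the values are never negative, their sums differ between libraries and are too large for TPM, and low values scale with gene length. No pair of libraries held identical values.

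Identifiers are TAIR locus tags, and 32809 of 33544 matched the RefSeq gene table of TAIR10.1. Coordinates, transcript lengths and 3′ UTRs come from that annotation, while the deposited tables hold no coordinates. Symbols were taken from the reference and otherwise from the tables. Groups were taken from the sample titles and genotype labels.

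The files hold normalized values, so the test planned for such values was used. Genes at 1 FPKM or more in at least 2 of 4 libraries (19308) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust estimation. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. A fold change on this scale understates the change of genes with low values. No fold is given against a group listed at 0. Read depth is not given. Relative depth was estimated from the most frequent ratio of values under 0.4 FPKM between libraries, over 503 to 534 genes, of which 28.8% to 30.0% lay within 0.05 (log2) of that ratio.

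The 20 gene lists (379 genes, 329 tested) were written before the data were examined, as were the tests, the other settings listed here and the rule for naming genes. Lists were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Camera at an estimated correlation takes its degrees of freedom from the libraries. With 4 libraries or fewer it can hardly call a list, whatever the correlation. The named genes are *ECT2*, the m6A machinery, *TTG1*, *SCAR2*, *ARPC2A*, up to 10 called genes with a symbol in each direction, and up to 4 genes of smallest p per list. Where fewer than 5 genes were called in a direction, the 5 with a symbol and the smallest p were named and said not to pass. The rule gave 109 genes, of which some are described. SAUR genes as a family and an iron-deficiency list were examined only after values had been seen. For the 3′ UTR motif, 10000 random lists were matched on length and level, and p-values were adjusted over 4 motifs.

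The procedure was tested on simulated data for this comparison, in 10 runs over 19308 genes with 200 changed genes each. Changes were placed only in genes above a minimum mean level, so the recovered shares do not cover tested genes at low values. Lowered values could fall below 0, which real values on this scale cannot. With variances drawn from the fitted prior, 92.3% of 16-fold, 32.3% of 4-fold and 0.147% of 2-fold changes were recovered, and 5.18% of calls were false. With each gene's shrunken variance used as its true variance, 98.3%, 91.8% and 10.3% were recovered, and 16.6% of calls were false. That second simulation was run first, and the other was added because its variances follow the model that limma fits, so the false share above the threshold remains a limit if real variances resemble the former. In both, a list of 15 genes raised by 0.5 (log2) was called by camera at a correlation of 0.01 in 10 of 10 runs and an unchanged list in 0. Simulated genes were drawn independently of each other. The lists called by camera between genotypes had estimated correlations of 0.18 to 0.99, so these runs do not give the rate of false list calls in the data.

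Alternatives were a replicate block, leaving out each library, TMM factors, computed on the FPKM from the published formula and divided out, quantile normalization, other pseudocounts and minimums, limma without trend, and removal of organelle genes with rescaling. Added after seeing the data were a restriction to protein-coding genes with transcripts of 500 nt or more, for which several lengths were looked at, library weights, leaving out each library for the locus and organelle results, and equal library medians. The last was added because the organelle rescaling and the left-out libraries gave implausible p-values.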

Results

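Polyadenylated RNA from whole seedlings of *Arabidopsis thaliana*, collected at 14 days, was sequenced from 2 genotypes: wild-type Col-0 and *ect2*, a T-DNA insertion mutant in the same background. Each genotype had 2 libraries, numbered 1 and 2. *ECT2* encodes a YTH-domain protein that binds N6-methyladenosine (m6A) in RNA. The comparison asks which transcripts differ in abundance when *ECT2* is disrupted. The files list FPKM for 33544 genes, and between 18908 and 19114 genes reached 1 FPKM in a library. Totals of reads per library are not given, so the absolute depth is unknown. Judged from the size of the lowest values, Col-0 replicate 1 was 1.46 times and *ect2* replicate 1 was 1.38 times as deep as Col-0 replicate 2, and *ect2* replicate 2 was 0.971 times as deep. The labels do not say whether replicates came from separately grown plants, so p-values measure only the spread between these libraries.

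*ECT2* (AT3G13460) was listed at 137 and 76.7 FPKM in the Col-0 libraries and at 9.07 and 8.58 FPKM in the *ect2* libraries. The gene lies on chromosome 3 from 4384563 to 4388592 on the minus strand of TAIR10.1, with an annotated 3′ UTR of 711 nt. Its mean was 107 ± 42.8 FPKM in Col-0 and 8.82 ± 0.35 FPKM in *ect2* (SD, n = 2 each), a ratio of 12.1. Both mutant libraries lay below both wild-type libraries. On the log2(FPKM + 1) scale the difference was -3.40 ± 0.33 (SE), which did not pass the threshold over all 19308 genes tested (limma, adjusted p = 0.153) and did pass when adjusted over the list of m6A genes alone (adjusted p = 0.00157). The call over all genes was reached without Col-0 replicate 1 (adjusted p = 0.0193) and without Col-0 replicate 2 (adjusted p = 0.00329), and not without either *ect2* library. With library medians set equal, these were 0.154 and 0.0495.

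**Figure D1:**
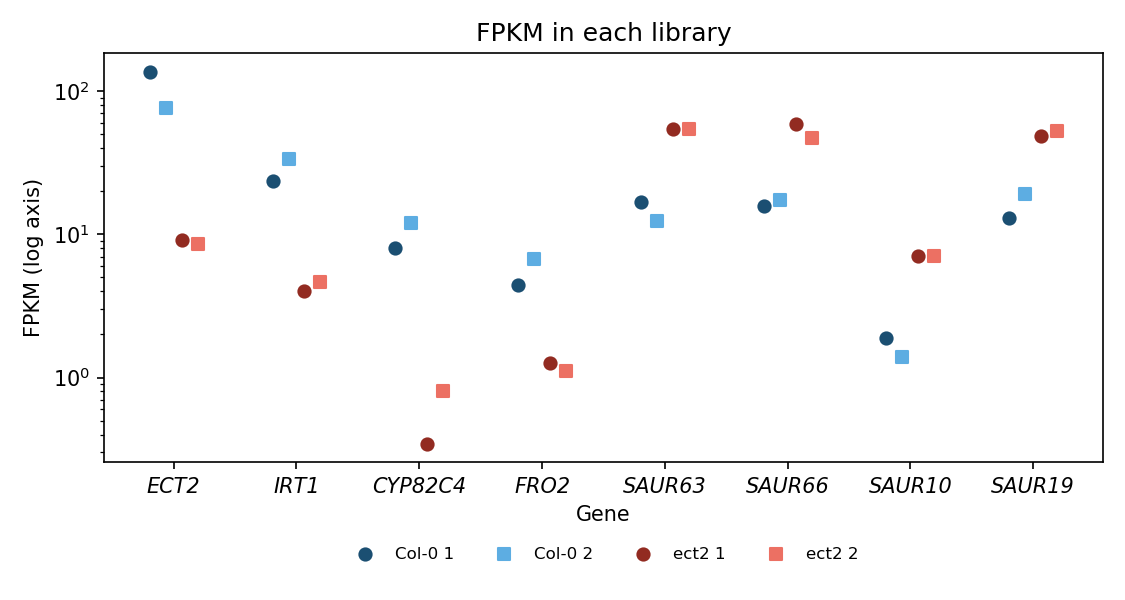
FPKM (log axis) of 8 genes in each of the 4 libraries, with circles for replicate 1 and squares for replicate 2, blue for Col-0 and red for ect2. ECT2 lies at 137 and 76.7 FPKM in Col-0 and at 9.07 and 8.58 FPKM in ect2. In all 8 genes the ect2 points lie on 1 side of the Col-0 points, as they do in 37.7% of all tested genes. The genes other than ECT2 were named for small p-values, so their separation follows from that choice. None of the 8 passed the test over all genes.

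Across all genes, limma called 5 of 19308 between *ect2* and Col-0 at an adjusted p below 0.05, 2 higher and 3 lower in *ect2*. All 5 were short genes listed at 0 in both libraries of 1 genotype. The same test called 2 genes when replicate 2 was set against replicate 1. It called 9 when Col-0 replicate 2 and *ect2* replicate 1 were set against the others. So 5 calls are within what other groupings of these libraries gave. None of the 5 has a gene symbol, so they are named here after their values were seen. The small nucleolar RNA gene AT2G20721 was listed at 0 in both Col-0 libraries and at 927 and 1280 FPKM in *ect2*. AT5G10336 was listed at 0 in Col-0 and at 32.6 and 48.4 FPKM in *ect2*. In the other direction, the small nucleolar RNA gene AT1G03506 was listed at 812 and 1178 FPKM in Col-0, AT3G26539 at 171 and 162 FPKM, and AT5G64401 at 17.9 and 25.5 FPKM, each at 0 in both *ect2* libraries. Their annotated transcripts measure 87 to 236 nt, and an exact 0 in such a table can be a failed estimate. Another 20 genes were listed at 0 in 1 library and at 20 FPKM or more in the other 3, most of them also short. Among these, AT1G03935, also of 87 nt, was listed in Col-0 at 1624.36 FPKM in replicate 1 and 1178.42 FPKM in replicate 2. AT1G03506 stood at 812.182 FPKM and the same 1178.42 FPKM. Such steps are what counts of very few reads would give, so a high FPKM of a short gene can rest on few reads. Read counts are not given. Restricted to protein-coding genes with a transcript of 500 nt or more, a choice made after seeing the data, limma called 0 genes, with 947 at an unadjusted p below 0.05. Over all genes tested, 938 had an unadjusted p below 0.05 (490 higher and 448 lower), where 965 would be so by chance. This number was 1229 without Col-0 replicate 1, 3950 without Col-0 replicate 2 (3794 with equal medians), 284 without *ect2* replicate 1 and 431 without *ect2* replicate 2. Without plastid and mitochondrial genes and with values rescaled to equal totals, the count was 175 (104 higher and 71 lower). That rescaling shifted whole libraries against each other, and the count was 5 once library medians were set equal.

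The genes with a symbol and the smallest p-values did not pass the threshold. Among the higher ones were 3 members of the SAUR family of auxin-induced growth genes. *SAUR63* (AT1G29440) was 14.7 ± 3.10 FPKM in Col-0 and 54.7 ± 0.12 FPKM in *ect2* (SD, n = 2 each), with an adjusted p of 0.498 from limma. *SAUR66* (AT1G29500) was 16.6 ± 1.00 and 53.0 ± 8.32 FPKM, and *SAUR10* (AT2G18010) was 1.64 ± 0.36 and 7.05 ± 0.02 FPKM (both adjusted p = 0.711, limma). *RSU1* (AT3G48130), annotated as a transcribed pseudogene, was listed at 0 in both Col-0 libraries and at 5.99 and 8.23 FPKM in *ect2*. *MIR863* (AT4G13494) was listed at 2.12 and 2.03 FPKM in *ect2* and practically 0 in Col-0. Among the lower ones, *IRT1* (AT4G19690), the main iron transporter of the root surface, was 28.5 ± 7.19 FPKM in Col-0 and 4.33 ± 0.48 FPKM in *ect2*. *CYP82C4* (AT4G31940), which acts in the iron-deficiency response, was 10.04 ± 2.81 and 0.578 ± 0.329 FPKM (both adjusted p = 0.235, limma). *FRO2* (AT1G01580), the ferric reductase of the root, was 5.60 ± 1.64 and 1.19 ± 0.10 FPKM (adjusted p = 0.791, limma). *SNOR30* (AT5G51174), a small nucleolar RNA gene of 116 nt, was listed at 56.7 and 159 FPKM in Col-0 and at 0 in both *ect2* libraries. Like the called genes, *RSU1*, *MIR863* and *SNOR30* were at or near 0 throughout a genotype, so the limit on values of 0 applies to them too. SAUR genes have close copies, and reads shared between copies make values of single members uncertain.

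Of the m6A machinery, which includes the methyltransferase subunits, the demethylases and the YTH-domain readers, 22 of 23 genes were tested and only *ECT2* was lower when adjusted over the list alone. None passed over all genes. The methyltransferase gene *MTA* (AT4G10760) was 6.86 ± 1.19 FPKM in Col-0 and 5.99 ± 0.29 FPKM in *ect2*, and *FIP37* (AT3G54170) was 7.81 ± 1.49 and 7.05 ± 0.21 FPKM. The demethylase gene *ALKBH10B* (AT4G02940) was 16.1 ± 5.05 and 13.9 ± 0.95 FPKM. The reader closest to *ECT2* in level, *ECT3* (AT5G61020), was 44.4 ± 10.2 and 44.1 ± 1.26 FPKM, and *ECT4* (AT1G55500) was 12.2 ± 5.70 and 9.94 ± 1.23 FPKM. *CPSF30* (AT1G30460), whose long form carries a YTH domain, was 5.90 ± 1.51 and 8.54 ± 1.55 FPKM. *ALKBH9A* was listed at 0 in all 4 libraries. As a set the list had a median log2 difference of -0.16 and was not called (camera, adjusted p = 0.249). The median was -0.0042 without Col-0 replicate 1, -0.24 without Col-0 replicate 2 and -0.092 without either *ect2* library, none called by camera. Fry called the list without Col-0 replicate 2 (adjusted p = 0.0288), and not with equal medians (adjusted p = 0.221).

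Trichome genes were examined because *ECT2* acts in trichome branching. *TTG1* (AT5G24520), a regulator of trichome fate, was 23.0 ± 1.21 FPKM in Col-0 and 25.5 ± 1.60 FPKM in *ect2*. *SCAR2* (AT2G38440) was 5.58 ± 0.25 and 5.62 ± 0.85 FPKM, and *ARPC2A* (AT1G30825), a subunit of the actin-nucleating ARP2/3 complex, was 10.13 ± 4.28 and 14.1 ± 1.56 FPKM. The list for trichome initiation and patterning had a median log2 difference of -0.11 over 18 genes (camera, adjusted p = 0.54), and that for branching and shape 0.040 over 22 genes (adjusted p = 0.598). Leaving out a library, these medians ranged from -0.14 to 0.046 and from -0.089 to 0.20. Both turned sign without Col-0 replicate 1. Of these lists, 0 genes passed over all genes or over the list alone. The largest difference was in *ETC2* (AT2G30420), a repressor of trichome initiation, at 6.02 ± 1.34 FPKM in Col-0 and 2.57 ± 0.72 FPKM in *ect2*. The list of mRNA decay genes had a median of -0.018 over 25 genes (adjusted p = 0.952), with 0 genes past the threshold over all genes or the list alone.

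Of 20 gene lists, 6 differed by camera with a preset correlation, and 0 differed with an estimated correlation (adjusted p = 0.876 for each of the 6) or by fry. The test with an estimated correlation has few degrees of freedom with 4 libraries. Its lack of calls, here and below, therefore does not show that correlation among genes accounts for the differences. No member of these 6 lists passed over all genes, and 1 member, *SAUR19*, passed adjusted over its list alone (adjusted p = 0.0105). Auxin-response genes had a positive difference in 9 of 9 members, with a median log2 difference of 0.88 (camera, adjusted p = 1.89e-06). *SAUR19* (AT5G18010) was 16.2 ± 4.42 FPKM in Col-0 and 50.9 ± 2.87 FPKM in *ect2*, and *IAA29* (AT4G32280) was 5.87 ± 6.60 and 23.0 ± 2.2 FPKM. Genes of the cell cycle and of endoreduplication, cell-cycle genes for short, had 1 positive difference among 29, with a median of -0.34 (camera, adjusted p = 3.44e-06). The list mixes both, so its median does not tell them apart. The mitotic cyclin gene *CYCB1;2* (AT5G06150) was 13.9 ± 1.2 and 8.01 ± 0.07 FPKM, and *KN* (AT1G08560), the cytokinesis syntaxin, was 44.3 ± 0.24 and 28.1 ± 2.45 FPKM. Jasmonate and wounding genes had a positive difference in 20 of 25 (median 0.36, camera, adjusted p = 0.00237). *JAZ10* (AT5G13220), a jasmonate-induced repressor, was 3.98 ± 1.49 and 8.25 ± 1.42 FPKM. The same camera test called 11 lists when replicate 2 was set against replicate 1 and 6 lists when the libraries were crossed, so 6 is within what the other groupings of these 4 libraries gave. Auxin-response genes (median 0.69, adjusted p = 0.0158), cell-cycle genes (-0.20, adjusted p = 0.00699) and jasmonate genes (0.47, adjusted p = 0.000105) were also called by camera in replicate 2 against replicate 1.

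The other 3 lists called by camera lost their calls without a single library, Col-0 replicate 1. Genes induced by darkness and sugar starvation had a median log2 difference of 1.34 over 9 genes (camera, adjusted p = 0.00104), anthocyanin and flavonoid genes -0.94 over 11 genes (adjusted p = 0.00237), and seed storage and oil body genes -1.42 over 7 genes (adjusted p = 0.0189). *ASN1* (AT3G47340), an asparagine synthetase induced by sugar starvation, was listed at 5.49 FPKM in Col-0 replicate 1 and at 315 FPKM in Col-0 replicate 2, beside 755 and 423 FPKM in *ect2*. *SESA2* (AT4G27150), a seed storage albumin gene, was listed at 56.7 FPKM in Col-0 replicate 1 and at 0.213, 0.315 and 1.07 FPKM in the other 3 libraries. *CHI* (AT3G55120), a flavonoid enzyme gene, was listed at 39.0 FPKM there and at 10.14 to 11.7 FPKM in the others. Without Col-0 replicate 1 the medians were 0.028 over 9 genes, 0.067 over 8 genes and 0.021 over 4 genes. Fewer anthocyanin and seed storage genes then passed the filter on low values, so their medians cover only part of each list. The seed storage genes also missed the threshold, at a median about as large, without *ect2* replicate 1 (-1.48, adjusted p = 0.0548, and 0.0283 with equal medians) and with a pseudocount of 0.1 (-1.45, adjusted p = 0.0619). With library weights the medians were smaller and not called by camera, at -0.48 for seed storage genes (adjusted p = 0.379) and -0.46 for anthocyanin genes (adjusted p = 0.176). Sugar-starvation genes also had a smaller median, 0.58, and were still called (camera, adjusted p = 0.0458, and 0.914 with an estimated correlation). Their median was 2.57 without Col-0 replicate 2. Auxin-response, jasmonate and cell-cycle genes stood apart in Col-0 replicate 1 as well, by -1.22, -0.67 and 0.37 from the mean of the other 3 libraries, whose medians spanned 0.54, 0.45 and 0.28. The median difference of auxin-response genes was 0.88 with that library and 0.46 without it (camera, adjusted p = 6.03e-05). Without it cell-cycle genes had a median of -0.22 (adjusted p = 0.00801) and jasmonate genes one of 0.31 (adjusted p = 0.0246), and none of these 3 lists was called with an estimated correlation (adjusted p = 0.991 for each). Without Col-0 replicate 2 the 3 medians were 1.52, -0.51 and 0.66. The jasmonate call was lost without *ect2* replicate 2 (median 0.21, adjusted p = 0.192). Without Col-0 replicate 1 and with equal medians the jasmonate median of 0.34 was close to the 0.36 over 4 libraries and narrowly missed the threshold (adjusted p = 0.0511).

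**Figure D2:**
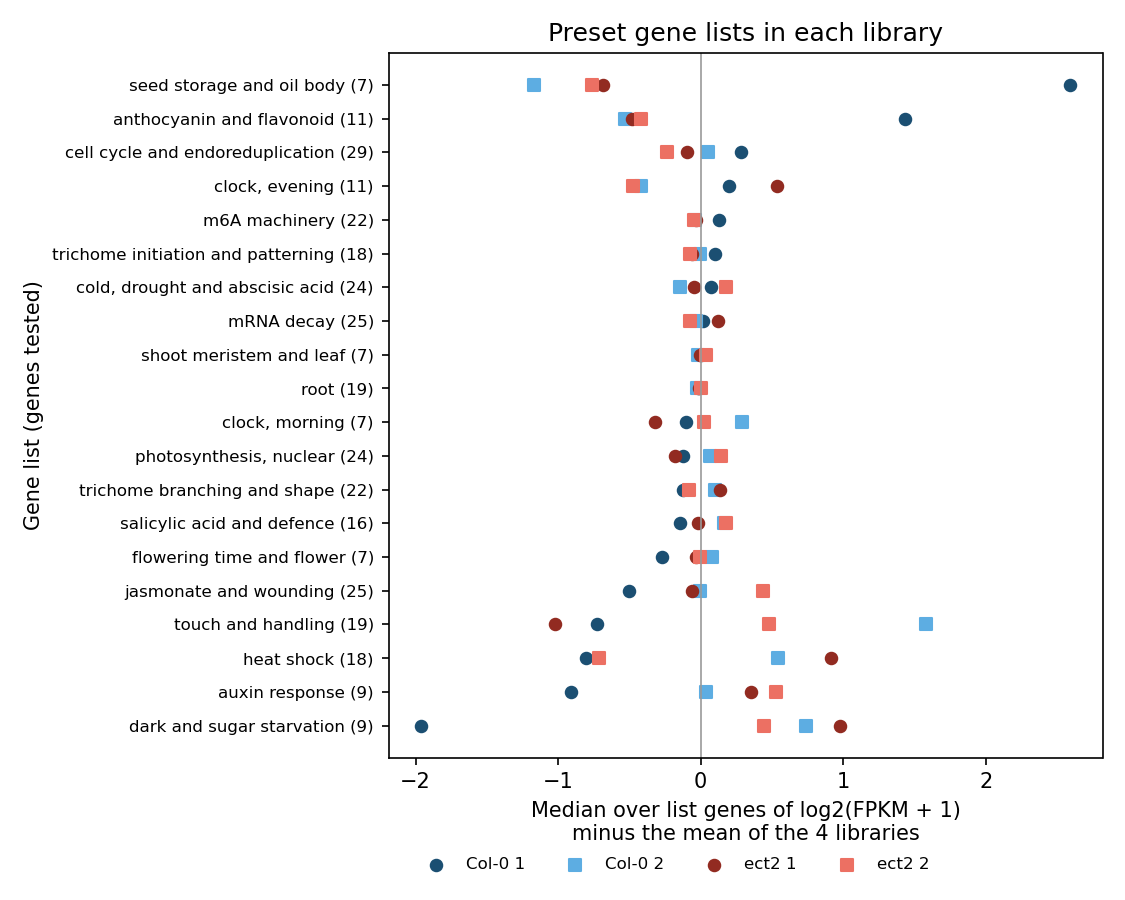
Median over the tested genes of each of 20 preset lists of log2(FPKM + 1) minus the mean of the 4 libraries, with 1 point per library (circles replicate 1, squares replicate 2, blue Col-0, red ect2) and no error bars. Col-0 replicate 1 lies at 2.59 for seed storage genes, 1.43 for anthocyanin genes and -1.96 for sugar-starvation genes, apart from the other 3 libraries.

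The other lists were not called by camera, with adjusted p between 0.0593 and 0.954. Touch and handling genes came closest (median -0.62 over 19 genes, adjusted p = 0.0593). Within both genotypes they were higher in replicate 2, by a median of 2.76 in Col-0 and 1.51 in *ect2*, so the replicates differed by more than the genotypes. Their median was -1.78 without Col-0 replicate 1 and -1.28 without *ect2* replicate 2, both called by camera (adjusted p = 8.77e-13 and 4.87e-05) and neither with an estimated correlation (adjusted p = 0.991 and 0.706). It was 0.40 without Col-0 replicate 2 and 0.0086 without *ect2* replicate 1, neither called (camera, adjusted p = 0.0609 and 0.873). *ZAT12* (AT5G59820), a touch-induced transcription factor gene, was listed at 30.1 and 181 FPKM in Col-0 and at 10.3 and 41.5 FPKM in *ect2*. Evening clock genes had a median of 0.14 over 11 genes and were lower in replicate 2, by -0.58 in Col-0 and -1.12 in *ect2*. Morning clock genes had a median of -0.19 over 7 genes, and heat-shock genes one of 0.34 over 18 genes. Without *ect2* replicate 2 camera called morning clock genes (median -0.80, adjusted p = 0.0115), evening clock genes (0.61, adjusted p = 0.000218) and heat-shock genes (1.13, adjusted p = 0.000156), and none with an estimated correlation (adjusted p = 0.706 for each). Without Col-0 replicate 1 it called evening clock genes (0.59, adjusted p = 0.0481, and 0.0771 with equal medians) and heat-shock genes in the opposite direction (-0.21, adjusted p = 0.00801), again not with an estimated correlation (adjusted p = 0.991 for both). Without *ect2* replicate 1 the evening clock median was negative (-0.33, adjusted p = 0.0548), and with equal medians it was called in that direction (-0.30, adjusted p = 0.0467, and 0.732 with an estimated correlation). Nuclear photosynthesis genes had a median of -0.017 over 24 genes, root genes 0.058 over 19, shoot meristem and leaf genes 0.020 over 7, and flowering genes -0.00045 over 7. Genes for cold, drought and abscisic acid had a median of 0.14 over 24 genes (0.17 and called by camera without *ect2* replicate 1, adjusted p = 0.01996, and adjusted p = 0.772 with an estimated correlation), and those for salicylic acid and defence 0.13 over 16. In the root list *IRT1* was lower when adjusted over the list alone (adjusted p = 0.00254). The shoot meristem list had a positive median with a negative mean of -0.12, and the root list likewise one of -0.078.

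Genes with the motif URUAY in the 3′ UTR, the motif reported for ECT2 binding, were compared with genes lacking it. The median log2 difference was -0.0025 over 15141 genes with the motif and -0.059 over 2782 genes without it, a difference of 0.057 that camera did not call (adjusted p = 0.269 over 4 motifs). The narrower motif UGUAY gave a difference of 0.056 (camera, adjusted p = 0.269) and the shuffled control motifs YATRT and YTRAT 0.044 and 0.024. All 4 medians with a motif lay at or above the 97.53rd percentile of lists matched on 3′ UTR length and level. Those lists were as large as the motif sets and drawn from the same genes, so they share most of their genes with them. They also ignore that genes can move together, so these percentiles are not separate support. Among genes above the median level the difference for URUAY was 0.096 (camera, adjusted p = 0.0442), beside 0.081 for UGUAY (adjusted p = 0.0799) and 0.066 and 0.050 for the control motifs, none of these called, and the difference between motif and controls was not tested. The motif is not a measured binding site.

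Within 1 Mb of *ECT2* on either side, 0 of 436 tested genes were called by limma, with 17 at an unadjusted p below 0.05 (3.90%, against 4.88% elsewhere, two-sided Fisher's exact test, p = 0.429). Plastid genes took 10.8% ± 4.21 of the summed FPKM in Col-0 and 14.5% ± 7.08 in *ect2* (SD, n = 2 each, exact permutation test, two-sided p = 0.667, where 0.333 is the smallest p possible). Mitochondrial genes took 0.22% ± 0.05 and 0.217% ± 0.123 (exact permutation test, p = 1). A single gene, AT2G01021, took between 23.8% and 36.8% of the sum in a library.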

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

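The settings with equal library medians, library weights and the length restriction were chosen after seeing the data. The 5 calls numbered 4 to 6 under TMM factors, quantile normalization, no filter, a minimum of 5, a pseudocount of 0.1, limma without trend and a threshold of 0.1. Library weights gave 8 calls, and protein-coding genes with transcripts of 500 nt or more gave 0, since short genes are then not tested. Removing organelle genes and rescaling to equal totals gave 175 calls and a p of 1.17e-16 for *ECT2*. These are not evidence of more changes. AT2G01021 takes much of each total, so rescaling moved library medians by -0.15 to 0.17 (log2), which raised the variance of all genes alike, and limma then tested on a median of 38284 degrees of freedom in place of 5.60. Putting the same shifts on the original values gave 142 calls, and setting medians equal after rescaling gave 5.

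Leaving out 1 library, where the lone library is assumed to vary like the other genotype, gave from 0 to 520 calls: 11 without Col-0 replicate 1, 520 without Col-0 replicate 2 and 0 without either *ect2* library. With equal medians these were 5, 18, 5 and 1, so most of the 520 also depended on small shifts between libraries. The *ECT2* difference ranged from -3.81 to -2.98 (-3.83 to -2.95 with equal medians), with adjusted p from 0.00329 to 1, and was -3.20 with library weights (adjusted p = 0.0352). Lists called by camera numbered 4 to 9 when a library was left out, and 0 with an estimated correlation. By fry it was 4 without Col-0 replicate 2 (0 with equal medians) and 0 without any other library. Leaving out a library, the median ranged from -0.21 to 1.13 for heat-shock genes, from -1.95 to 0.067 for anthocyanin genes and from -3.30 to 0.021 for seed storage genes. Without Col-0 replicate 1 it was -0.21, 0.067 and 0.021 (-0.18, 0.10 and 0.054 with equal medians). For evening clock genes it was -0.30 without *ect2* replicate 1 with equal medians. Each of these is opposite in sign to the value over 4 libraries, as was -0.092 for heat-shock genes with library weights. Smaller medians turned sign as well when a library was left out, among them those of both trichome lists, mRNA decay and nuclear photosynthesis genes. The cause was not tested. For the 3′ UTR motif the difference was 0.096 among genes above the median level, the cause of which was not tested, and 0.037 to 0.081 when a library was left out. Over 4 libraries 0 genes were called within 1 Mb, 3 Mb or 200 kb of *ECT2*. Leaving out a library, calls within 1 Mb numbered 0 to 12, the 12 without Col-0 replicate 2 (Fisher's exact test, p = 0.881). The plastid difference ranged from -1.29 to 8.72 percentage points.

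The labels do not say whether replicate numbers mark a batch. Deviations of same-numbered libraries correlated at 0.0138 across genes, but touch, evening clock and jasmonate genes differed between the numbers in the same direction in both genotypes, so shared handling is not excluded. With a replicate block 6 genes and 7 lists were called (0 lists with an estimated correlation), and *ECT2* stood at -3.40 (adjusted p = 0.136). Camera called touch and handling genes with the block (adjusted p = 1.75e-06), TMM factors (0.0464), organelle genes removed and equal medians (0.0394) and library weights (0.000647), but not with an estimated correlation (adjusted p = 0.822 to 0.971). Unknown read depth limits what can be said of genes at low values.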

Other observations

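The tests in this part were chosen after the results were seen, and the iron-deficiency genes include 6 whose values prompted the list. Genes of the iron-deficiency response had a negative difference in *ect2* in 21 of 21 members, with a median log2 difference of -1.29 (camera, p = 3.53e-15, and p = 0.0132 with an estimated correlation). The estimated correlation was -0.027, below the preset 0.01, so the larger p came with the fewer degrees of freedom of that test. Among the 15 members not seen first, 8 had both *ect2* libraries below both Col-0 libraries, as did 20.2% of all genes tested, where chance gives 16.7%. The median was -0.84 without Col-0 replicate 1. With an estimated correlation p was 0.0728 to 0.0991 when a library was left out, with or without equal medians, and 0.0700 with the replicate block. *IMA1* was listed at 41.7 and 13.7 FPKM in Col-0 and at 4.61 and 4.94 FPKM in *ect2*. *IMA3*, like *IMA1* a gene for a peptide that promotes iron uptake, was listed at 99.3 and 23.4 FPKM in Col-0 and at 3.35 and 9.16 FPKM in *ect2*. The transcription factor gene *bHLH39* was listed at 6.77 and 3.45 FPKM in Col-0 and at 1.31 and 1.19 FPKM in *ect2*. *FIT*, the central regulator of iron uptake, was 4.23 ± 0.09 and 3.65 ± 0.46 FPKM (SD, n = 2 each). No member passed limma over all genes. The ferritin genes *FER1* to *FER4*, whose transcripts are known to increase with iron supply, had differences of 0.52, 0.0063, -0.33 and -0.20, with overlapping libraries in all 4. As a hypothesis, the iron-deficiency response may be lower as a group in these *ect2* seedlings. The 15 members not seen first had a median of -0.68, where 95% of 10000 matched random lists lay between -0.21 and 0.21. Without Col-0 replicate 1 the difference was negative in 12 of 14 (median -0.46). These 15 belong to the same response as the 6 seen first and were read in the same libraries, so they are not an independent test. The random lists draw unrelated genes and ignore such shared regulation. With an estimated correlation these 15 had a p of 0.0343, of 0.113 with the replicate block, and of 0.123 to 0.188 when a library was left out. Whether plants of both genotypes met the same iron supply is not stated in the labels.

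SAUR genes, many of which are induced by auxin and promote cell elongation, had a positive difference in 53 of 66 members, with a median of 0.63. Among 126 families grouped by symbol SAUR had the smallest camera p (3.35e-19, adjusted p = 4.22e-17). With an estimated correlation the adjusted p was 0.862, and by fry 0.702. The estimated correlation was 0.0031, below the preset 0.01, so the loss of the camera call does not show correlation among members. Of the other groupings of the libraries, the smallest family p was 8.45e-06 and 1.22e-06, and SAUR had a p of 0.381 and 0.929. SAUR was picked for its difference between genotypes, so its larger p elsewhere is not separate support. Camera called 16 of 126 families between genotypes, 8 between replicate numbers and 15 in the crossed grouping. The median of the family as a whole was also 0.63 without Col-0 replicate 1, though not that of every part of the family, as given below. This lay above the 95% range of matched random lists, but those draw unrelated genes and ignore that family members can move together. That range therefore cannot decide whether a single library moved the family. Reads shared between neighbouring copies could contribute and cannot be told apart from a change of each copy: members with no other SAUR gene within 50 kb had a median of 0.35, above the range of random lists, but 0.079 and inside that range without Col-0 replicate 1, while members with neighbours had 1.35. Harvest at another time of day is also open, since evening clock genes differed by 0.14 between genotypes and by more between replicates. A higher SAUR level in *ect2* is one hypothesis among these.

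All 5 called genes were listed at 0 in both libraries of 1 genotype. Short genes listed at 0 by chance could give such a pattern. Genes at 0 in both libraries of 1 side and at 2 FPKM or more in both of the other numbered 13 between genotypes, 13 between replicate numbers and 16 in the crossed grouping. Calls in these groupings numbered 5, 2 and 9. With 3 groupings of 4 libraries, no share below 0.05 can be reached. The libraries were made from mRNA isolated on oligo(dT) beads, and values of such short genes can rest on very few reads. A genotype effect on small nucleolar RNAs can therefore not be judged from these values.

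Col-0 replicate 1 stood apart on the first principal component, which took 51.6% of the variance, and correlated with the other libraries at 0.932 to 0.940 across genes, which are not independent replicates, where the others correlated at 0.956 to 0.966. A mislabelled *ect2* library is argued against, since *ECT2* there was 15.1 times the higher *ect2* library. Depth alone is argued against, since *ect2* replicate 1 lay within 1.06-fold of its relative depth. Seed material in that sample stays open. The median of 7 storage protein genes was 32.5 FPKM there and at most 0.865 FPKM in another library, while the higher of *EM1* and *EM6*, abundant in mature seeds, stood at 0.726% of that median, and the ratio in seeds was not measured here. A difference in age, light or sugar supply of those seedlings may also remain and was not tested.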
